A study of Arabidopsis thaliana with 24 samples.

How the data were processed

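Arabidopsis thaliana Col-0 plants were grown in hydroponic solution, and part of them received 100 mM NaCl for 48 h, per the labels' protocols. Shoots and roots were separated and immersed in buffer with 0.75% dimethyl sulfate (DMS, about 75 mM) for 5 min, or in buffer alone. DMS enters living tissue and methylates the pairing face of unpaired adenines and cytosines, and reverse transcription stops one base before each such methyl group. Structure-seq2 reads these stops genome-wide, and a reactivity is made by setting the stops of treated libraries against those of libraries without DMS. Per the labels, poly(A)-selected RNA was reverse transcribed from random hexamers, and 24 libraries were made from 3 biological replicates in each of 8 groups of tissue, salt and DMS. Each of the 4 conditions, shoot or root with or without salt, thus rests on 6 libraries.

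The deposited table held 12978 transcripts, each with 1 value per condition. Per the file headers, 3 of its measures are scores of DMS reactivity on a scale set by the authors: the highest reactivity of a transcript, its mean and its standard deviation between bases. The fourth deposited measure, per the file headers, is the Gini index, a fraction from 0 for even reactivity along a transcript to 1 for reactivity held by few bases. The authors combined the replicates before deposit. How they did so, the aligner, the genome build, the bases counted, the normalization of reactivity and the coverage filter are not given in the sources used here. Reactivities of exactly 7 were the highest in all 4 conditions, as an upper bound on single bases would give. Read depth per library or transcript is unknown, so no interval for counting error could be given.

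With 1 value per condition no spread between replicates could be computed. The design fixed for that case was used: differences are described by size, without p-values. One isoform per locus was kept, the lowest-numbered of those in the table, giving 8956 loci. For each comparison the log2 ratio of mean reactivity was taken without pseudocount over loci whose mean over both conditions reached 0.1. A ratio of 1.5-fold or more was counted as large. The tissue difference of the salt effect is the root log2 ratio minus the shoot log2 ratio. Intervals of medians (95%, binomial order statistics) and of percentages (95%, Wilson) treat loci as independent and leave out replicate variation, so they describe the table and do not test the treatment.

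Before the data were examined, 10 gene lists were fixed by locus, and chloroplast-encoded and mitochondria-encoded transcripts were added by the prefix of their locus code, making 12 lists. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on deciles of mean reactivity over the conditions compared. A list is said to stand apart when its median fell below percentile 2.5 or above percentile 97.5, which is a description of these libraries. Log2 ratios varied with mean reactivity, so the medians of matched random lists could differ from the median of all transcripts, most of all for photosynthesis, chloroplast-encoded and ribosomal protein transcripts between tissues. The same was done for differences of the Gini index. Gene symbols came from the lists or, by locus, from the TAIR10.1 reference table, which held 8893 of the 8956 loci (99.3%). The build used by the authors is not given in the sources used here, so no coordinates are printed.

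Genes named in the text were chosen by a rule fixed in advance: per comparison the 8 largest log2 ratios in each direction, the 2 highest and 2 lowest members of each list, the 5 largest differences between tissues each way, and 9 salt and ion transport genes wherever measured. Of those 9, RD29A, NHX1 and AVP1 were analysed here. Transcripts of near-identical genes, such as RBCS, LHCB1, KIN1 and KIN2, PIP2;2 and PIP2;3, polyubiquitin or actin, can share reads, and their values are uncertain to that extent. In all, 76 transcripts had values identical to those of another transcript in all 4 conditions.

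Alternatives fixed in advance were no minimum or a minimum of 0.2 for mean reactivity, all isoforms, log2 ratios centred on their median, a pseudocount of 0.1, size limits of 1.25-fold and 2-fold, transcripts measured in all 4 conditions, random lists without matching, and the standard deviation over the mean in place of the Gini index. A limit of 0.9 on the Gini index and counting loci with identical values once were 2 settings chosen after seeing the data. Alternatives for lists used 2000 random lists. With all isoforms, isoforms of 1 locus counted as separate list members, while random lists drew transcripts singly. Percentiles in that setting can therefore be too extreme. The calculations were tested on simulated data in which 200 of the 8956 loci were changed by known factors: 2-fold changes were recovered in 100% of loci for salt in shoot, 99.5% for salt in root, 97.5% for root against shoot without salt and 100% with salt. Changes of 1.5-fold, which lie on the limit, were recovered in 53%, 57%, 47.5% and 40.5%. Over the simulated sizes, 35 to 38 unchanged loci passed the 1.5-fold limit for root against shoot without salt and 7 to 14 with salt, and 0 for salt in either tissue. The simulated ratios of unchanged loci were normal around 0, with a spread taken from the middle of the observed ratios. They held no replicate error, shallow coverage or extreme values, so these counts are not false-call rates for the observed data. Of 100 random lists of 20 loci in the shoot salt comparison, 3 stood apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.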

Results

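DMS reactivity, a measure of how open the bases of an RNA are in the living tissue, was compared between shoots and roots of Arabidopsis Col-0 plants kept in control solution or exposed to 100 mM NaCl for 48 h. The series asks, from its title, whether salt changes RNA structure differently in the 2 tissues. The 4 conditions were each measured from 3 replicate libraries with DMS and 3 without, and the authors combined the replicates into 1 value per transcript and condition. A higher mean reactivity is taken here to stand for more unpaired or accessible bases, and a higher Gini index for reactivity held by fewer bases. How reactivity was normalized is unknown, and in control shoots mean reactivity closely followed the Gini index (Spearman's rho -0.993). Ratios against control shoots may therefore reflect the scale and not only how open the bases are. No difference given here could be set against the spread between replicates, and read depth is unknown. Median mean reactivity over 8956 loci was 0.273 in control shoots, 0.266 in salt-treated shoots, 0.198 in control roots and 0.210 in salt-treated roots.

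The shoot comparison asks which transcripts were more or less reactive after salt. The largest group difference in named genes was among the salt, dehydration and abscisic acid response genes, which were less reactive with salt. Of the 30 members analysed, of 51 listed, 28 had a lower mean reactivity with salt (26 lay below the median of all transcripts), and 10 were lower by at least 1.5-fold. Their median log2 ratio was -0.37, at percentile 0 among matched random lists. LTI30, a dehydrin, had the lowest ratio of the list, with 0.425 times its control reactivity (log2 ratio -1.24). GOLS2, a galactinol synthase of raffinose synthesis, stood at -1.08, KIN1, a cold- and abscisic acid-induced gene, at -0.89, and the NAC transcription factor RD26 at -0.86. HAB1, a protein phosphatase that restrains abscisic acid signalling, was at -0.86, and RD29A, a desiccation-induced gene, at -0.74. The highest members were ERD15 at 0.15 and CYP707A3, an abscisic acid 8'-hydroxylase, at 0.06. AFP1, which encodes a binding partner of the abscisic acid regulator ABI5 and was on no list, stood at -1.19.

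Photosynthesis transcripts of the nuclear genome were more reactive in salt-treated shoots. All but 1 of the 26 members analysed, of 55 listed, had a ratio above 0, the median log2 ratio was 0.13 and the percentile was 99.6, while matched random lists had medians of 0.019 to 0.111. LHCB1.5, a light-harvesting protein of photosystem II, reached 0.38 and PSAN, a photosystem I subunit, 0.31. RBCS1A, a Rubisco small subunit, was at -0.01. The 14 chloroplast-encoded transcripts, which had only 9 distinct sets of values because several loci share identical ones, had a median of 0.10 at percentile 100. They ranged from -0.50 for ATCG00960 and ATCG01170 to 0.32 for ATCG01310 and ATCG00830.

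Aquaporins, the channels that carry water across membranes, were lower as a list in salt-treated shoots, with a median log2 ratio of -0.10 over 14 members at percentile 0.05. Their members went both ways, 8 below 0 and 6 above. PIP2;3 at -0.60 and PIP2;2 at -0.45 lay lowest, and PIP2;8 at 0.28 and TIP2;1 at 0.14 highest. Heat shock proteins and chaperones had a median of -0.08 over 12 members at percentile 0.13, with HSP90.1 at -0.30 and HSC70-3 at -0.25, and CPN60A, a chloroplast chaperonin, at 0.25. Neither list stood apart when random lists were not matched on reactivity, with percentiles of 2.5 for aquaporins and 9.3 for heat shock proteins. Root-expressed markers, only 4 of 20 analysed, stood at 0.17 and percentile 99.7.

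Lists that did not stand apart in shoot were ion transport and salt tolerance (median -0.05, percentile 5.0), reactive oxygen scavenging (-0.04, percentile 4.54), RNA-binding proteins and helicases (-0.03, percentile 6.07), cytosolic ribosomal proteins (0.01, percentile 12.0), housekeeping genes (-0.01, percentile 7.55) and mitochondria-encoded transcripts (-0.11, percentile 31.9). With all isoforms, ion transport (percentile 0.30), RNA-binding proteins (0.20) and housekeeping genes (0) did stand apart. Among ion transport genes, the vacuolar sodium/proton exchanger NHX1 was at -0.33, the plasma membrane proton pump AHA2 at -0.22 and the vacuolar proton pump AVP1 at 0.03. DHAR1, a dehydroascorbate reductase, was at -0.28 and the catalase CAT3 at 0.10. The RNA chaperone CSP3 was at -0.14 and the glycine-rich RNA-binding protein GRP8 at 0.15.

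Across all 8956 loci the shoot shift was small, with a median log2 ratio of -0.035 (95% interval -0.038 to -0.032) and 37.3% of loci (36.3 to 38.3) above 0. Only 8 loci were higher and 39 lower by at least 1.5-fold. These counts depended on the setting, with 2 and 5 under a pseudocount of 0.1, 13 lower under a minimum mean reactivity of 0.2, and 13 and 59 with all isoforms. The highest ratio was that of SEN1, a senescence-associated and dark-inducible gene, with 2.11 times its control reactivity. The proline dehydrogenase gene ERD5 was at 0.65 and DIN10, a dark-inducible gene of the raffinose synthase family, at 0.63, with AT1G15125 at 0.87, AT5G62360 at 0.71 and AT1G27020 at 0.67. The lowest ratios of all, in AT3G52700 (-2.33) and the non-coding retrotransposon SADHU2-1 (-2.27), and the high ones of AT5G10660 (0.71) and AT2G41231 (0.59), belonged to transcripts with Gini indices above 0.9, whose mean rests on few bases.

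The root comparison asks the same of root transcripts, and there the photosynthesis list lay on the opposite side of 0. All 26 members had a lower mean reactivity with salt, 16 of them by at least 1.5-fold, with a median log2 ratio of -0.66 at percentile 0. Their root means rest on fewer bases than their shoot means. The median Gini index was 0.803 without salt and 0.800 with salt in root, against 0.516 and 0.563 in shoot. Depth is unknown, so an effect of shallow coverage on these ratios was not tested. The Rubisco small subunits RBCS3B and RBCS1A had 0.454 and 0.490 times their control reactivity, and LHCB1.5 had 0.501 times. The smallest differences were in PSAN at -0.24 and FD2, the leaf ferredoxin, at -0.28. PSBTN, a photosystem II subunit outside the list, was at -0.98. Chloroplast-encoded transcripts, with only 9 distinct sets of values, had a median of -0.26 at percentile 0. There were 8 members below 0 and 6 above, from -0.96 for ATCG00960 and ATCG01170 to 0.26 for ATCG01240 and ATCG00900. With a minimum mean reactivity of 0.2 the chloroplast list, of 12 loci, no longer stood apart (percentile 12.8).

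The salt, dehydration and abscisic acid list was also lower in salt-treated roots, with a median log2 ratio of -0.10 at percentile 0, 19 of 30 members below 0 (24 below the median of all transcripts) and 2 lower by at least 1.5-fold. KIN1 at -1.01 and its close relative KIN2 at -0.59 lay lowest, RD29A stood at -0.43, and ERD15 at 0.25 and ERD4 at 0.17 lay highest. Mitochondria-encoded transcripts, 6 loci, stood at -0.04 and percentile 1.34.

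Aquaporins and cytosolic ribosomal proteins were more reactive in salt-treated roots. All 13 aquaporins analysed lay above 0, with a median of 0.20 at percentile 99.8, led by TIP2;1, a tonoplast aquaporin, at 0.47 and PIP1;3 at 0.38. All 25 ribosomal protein transcripts lay above 0, with a median of 0.18 at percentile 99.98, from RPS6A and RPL24B at 0.03 to RPL16A and RPS15AA at 0.28. Relative to the median of all root transcripts, 11 of the 13 aquaporins and 22 of the 25 ribosomal protein transcripts were higher, and PIP1;4, at 0.06, was lower. The lists of ion transport (0.07, percentile 27.2), reactive oxygen scavenging (0.07, percentile 21.3), heat shock proteins (0.04, percentile 7.90), RNA-binding proteins (0.08, percentile 36.1), housekeeping genes (0.11, percentile 70.9) and root-expressed markers (0.07, percentile 38.8) did not stand apart, and all but the housekeeping list lay slightly under the median of all transcripts. NHX1 was at 0.01, AVP1 at 0.14 and HSP90.1 at -0.41.

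Root transcripts as a whole were slightly more reactive with salt. The median log2 ratio over 8891 loci was 0.088 (0.085 to 0.091), and 80.1% of loci (79.2 to 80.9) lay above 0. Only 9 were higher and 38 lower by at least 1.5-fold, or 1 and 17 under a pseudocount of 0.1, and 4 were higher under a minimum of 0.2 or after centring. The highest were AT2G47570 at 1.32, whose Gini index was above 0.96 in every condition, AT1G76800 at 0.89, AT3G25190 at 0.86 and AT2G30230 at 0.72, followed by AT1G23205 at 0.65, the methyltransferase gene HOL1 at 0.63, AT3G52520 at 0.60 and AT5G62360 at 0.59. AT1G20015 (-1.38), with a Gini index of 0.960 in salt-treated root, and GRX480, a glutaredoxin gene (-1.16), were the lowest.

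**Figure D1:**
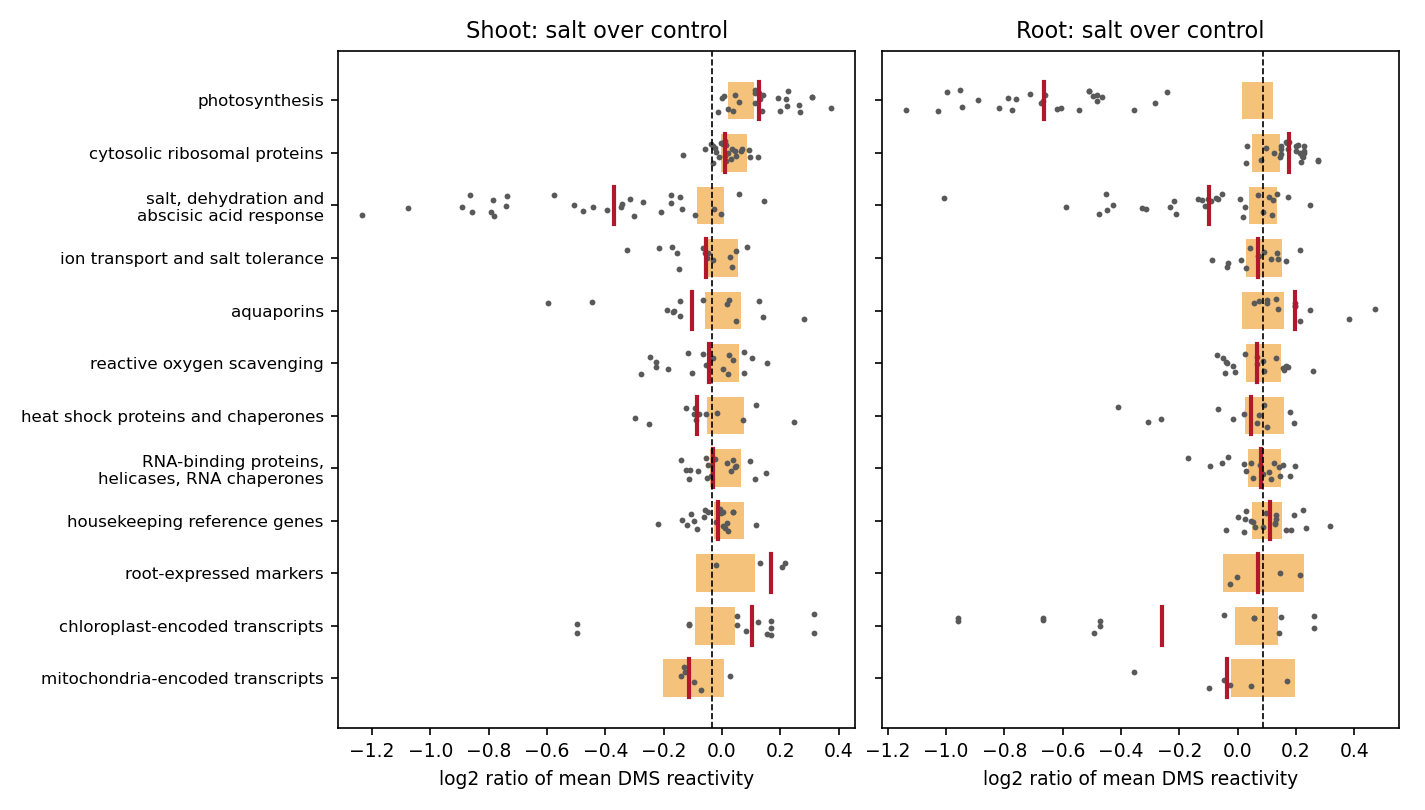
Log2 ratio of mean DMS reactivity, salt over control, of each analysed member (points) of the 12 gene lists in shoot (left) and root (right). Red bars are list medians, orange bands the middle 95% of medians of 10000 matched random lists, and the dashed line the median of all transcripts; photosynthesis members lie at a median of 0.13 in shoot and -0.66 in root, and the salt response list at -0.37 and -0.10.

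The difference between the tissues in the salt effect was greatest for photosynthesis transcripts among the lists. All 26 had a lower salt ratio in root than in shoot, 20 of them by at least 1.5-fold, with a median difference of -0.80 at percentile 0. LHCB1.5 differed by -1.37, LHCB1.2 by -1.18 and RBCS3B by -1.15. Chloroplast-encoded transcripts had a median difference of -0.36 at percentile 0. The salt and abscisic acid list went the other way. Its median difference was 0.23 at percentile 99.99, 26 of 30 members had the higher ratio in root, and 7 did so by at least 1.5-fold. Of all loci 82.0% had the higher ratio in root, so that count is near the general share. Relative to the median difference of all transcripts, 21 members lay above and 9 below. LTI30, at -1.24 in shoot and 0.12 in root, differed by 1.36, AFP1 by 1.01, RD26 by 0.79 and NHX1 by 0.34, whereas KIN2 differed by -0.42. Aquaporins had a median difference of 0.26 at percentile 99.99, with PIP2;3 at 0.70 and TIP2;2 at 0.41. The median difference of cytosolic ribosomal proteins was 0.18 at percentile 99.95, but at 96.2 without matching, where they no longer stood apart.

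Ion transport (0.14, percentile 78.5), reactive oxygen scavenging (0.13, percentile 82.1), heat shock proteins (0.05, percentile 11.3), RNA-binding proteins (0.09, percentile 48.0), housekeeping genes (0.14, percentile 89.1), root-expressed markers (0.002, percentile 3.59) and mitochondria-encoded transcripts (0.08, percentile 7.95) did not stand apart in this difference. The median difference of all 8891 loci was 0.12 (0.121 to 0.128), and after centring each tissue on its median it was 0.0012. The count of differences of at least 1.5-fold was 55 with the higher ratio in root and 41 with the lower, or 15 and 64 after centring. Only 5 were higher under a pseudocount of 0.1 and 4 under a minimum of 0.2. SADHU2-1 (1.70) and AT2G47570 (1.43), both with high Gini indices, and AT1G68500 (0.98) were among the highest, and AT5G10660 (-1.24) and AT1G20015 (-1.15) among the lowest.

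Salt effects in the tissues were weakly related across transcripts, with Pearson's r of 0.212 and Spearman's rho of 0.204 over 8891 loci, which are not independent replicates. Of the 36 loci lower by at least 1.5-fold in shoot and the 38 in root, among those compared in both tissues, KIN1 and AT1G55710 were lower in both, against 0.154 loci from independent lists. AT5G62360 was the 1 locus higher in both, of 8 and 9, against 0.0081. No library was shared by the salt comparisons of the 2 tissues. AT1G55710 was named after its values were seen.

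**Figure D2:**
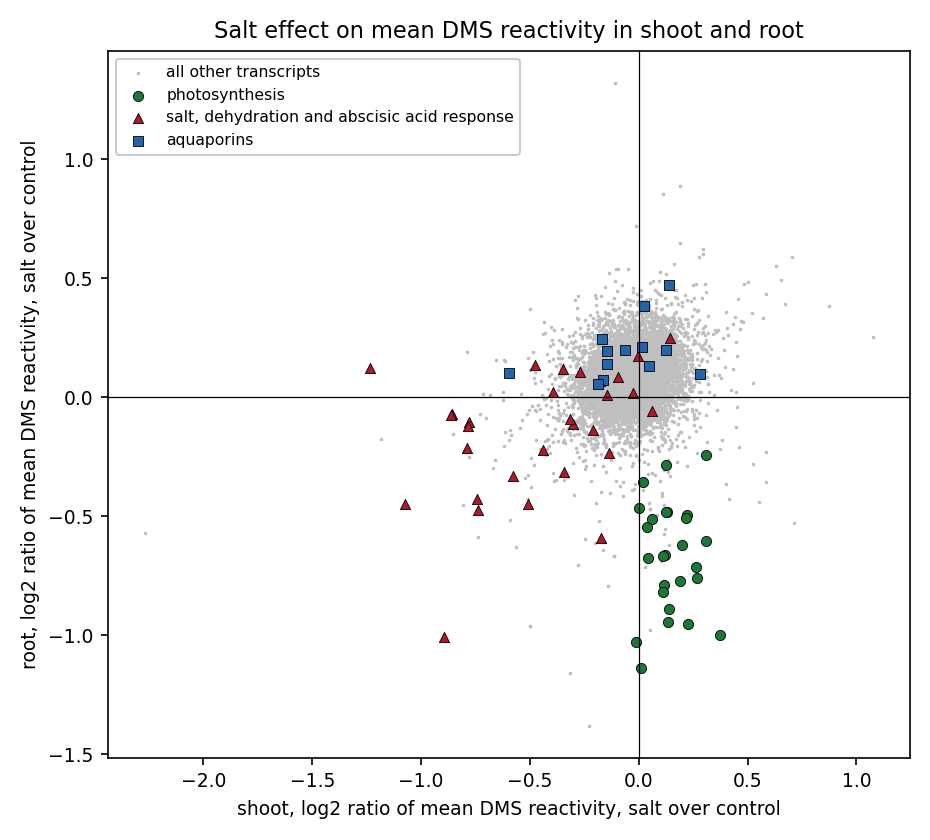
Log2 ratio of mean DMS reactivity, salt over control, in shoot (horizontal axis) and root (vertical axis) for 8891 loci (grey), with photosynthesis (green circles), salt response (red triangles) and aquaporin (blue squares) members marked. Photosynthesis members lie below 0 in root, with a median of -0.66, and salt response members reach -1.24 in shoot.

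Between tissues without salt, photosynthesis and chloroplast-encoded transcripts stood out as more reactive in root, against a lower reactivity of most other transcripts there. Only 7.44% of loci (6.91 to 8.00) lay above 0, with a median log2 ratio of root over shoot of -0.45 (-0.459 to -0.449) over 8954 loci, so lists are also given relative to that median. Control roots enter this ratio and the salt ratio of roots. The 26 photosynthesis transcripts had a median of 0.47, or 0.92 above that of all transcripts. Matched random lists had medians of -0.153 to 0.241, also well above that of all transcripts, and the list stood at percentile 100 among them. Of its members 5 were higher in root by at least 1.5-fold. Their median Gini index was 0.803 in control roots and 0.516 in control shoots, so the root means rest on fewer bases. LHCB1.5 was at 0.80 and LHCB6 at 0.75, and PSBR at -0.29 lay lowest. The 14 chloroplast-encoded transcripts all lay above 0, at a median of 0.51, or 0.97 above all transcripts, while matched random lists had medians of -0.343 to 0.240. Of these 7 were higher by at least 1.5-fold, led by ATCG01180 and ATCG00950 at 0.89. They had only 9 distinct sets of values, so these counts include repeats. The list was taken by code prefix and not divided by kind of RNA. SHM1, a mitochondrial serine hydroxymethyltransferase of photorespiration, was at 0.89, and LP1, a lipid transfer protein gene, had 2.07 times its shoot reactivity.

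Transcripts of aquaporins and of root-expressed markers were less reactive in root. Aquaporins had a median 0.31 below that of all transcripts at percentile 0, with PIP2;2 at -1.70 and PIP2;3 at -1.41, and 10 of 14 were lower by at least 1.5-fold. The 4 root-expressed markers had a median 0.85 below, with NAI2 at -1.43, PBP1 at -1.39 and PYK10, an endoplasmic reticulum body beta-glucosidase, at -1.23, whereas the ammonium transporter AMT1;1 was at -0.33. Housekeeping genes lay 0.08 below all transcripts (percentile 0.04) and cytosolic ribosomal proteins 0.07 below (percentile 0), with ACT8 at -1.19, UBQ10 at -0.76 and RPL23AB at -0.78. Matched random lists had medians of -0.464 to -0.189 for housekeeping genes and -0.432 to -0.122 for ribosomal proteins, and neither list stood apart without matching, at percentiles 6.25 and 8.03. Reactive oxygen scavenging (-0.03 relative to all transcripts, percentile 3.65), the salt list (0.09, percentile 89.3), ion transport (-0.01, percentile 14.2), heat shock proteins (0.02, percentile 17.2), RNA-binding proteins (0.003, percentile 9.45) and mitochondria-encoded transcripts (-0.17, percentile 23.56) did not stand apart. The call for the salt list depended on the setting, with percentile 97.65 without matching but 1.6 with all isoforms, where its median lay on the other side of all transcripts at -0.040. With all isoforms, where isoforms of 1 locus counted as separate members, ion transport (percentile 0.25) and reactive oxygen scavenging (0) also stood apart. LTI30 was at -1.37 and KIN2 at 0.41, and the chloroplast RNA-binding protein CP31A at 0.58.

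By the 1.5-fold limit 42 loci were higher and 2263 lower in root, or 433 and 180 once ratios were centred and 16 and 377 under a pseudocount of 0.1. The counts in each direction thus depended on where the ratios were centred. Simulated unchanged loci, of which 35 to 38 passed that limit, were centred on 0, whereas the observed ratios had a median of -0.45. They are therefore no background for the observed counts. The lowest of all were AT1G22690 (-2.49), AT4G38080 (-2.24), MLP34 (-1.99), the metallothionein gene MT1C (-1.92), the pectin methylesterase PMEPCRA (-1.89), AT2G22510 (-1.89), AT2G47570 (-1.88) and AT1G09740 (-1.86). Of these AT1G22690 and AT2G47570 had Gini indices of 0.985 and 0.992 in control root, so their means rest on few bases. Among the highest were AT5G10660 (2.59), TPPI, a trehalose-6-phosphate phosphatase (1.87), AT2G41231 (1.54) and AT3G12955 (1.01), all with Gini indices above 0.9 in control shoots.

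With salt in both tissues, the photosynthesis list no longer had the higher reactivity in root. Its median log2 ratio was -0.34, 0.017 below that of all transcripts, with 13 members above and 13 below that median. The matched random lists had medians of -0.27 to 0.11, so the percentile was 0.03, but it was 32.6 without matching. RBCS1A was at -0.99 and PSAG at -0.97, and LHCB4.1 at 0.15. Chloroplast-encoded transcripts stayed 0.63 above all transcripts at percentile 100. The salt and abscisic acid list had a median of -0.11, which lay 0.21 above that of all transcripts at percentile 100, with 25 of 30 members above it and RD29A at 0.46 and the phosphatase gene ABI2 at 0.36, and CYP707A3 at -0.57. Aquaporins were 0.24 below at percentile 0, with PIP1;1 at -1.10 and PIP2;2 at -1.05. Root-expressed markers were 1.08 below, with PYK10 at -1.45.

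Housekeeping genes (0.09 below all transcripts, percentile 0.52) and ribosomal proteins (0.05 below, percentile 0.30) stood apart with salt also, but not without matching (percentiles 3.30 and 14.35). Ion transport (percentile 55.9), reactive oxygen scavenging (7.0), heat shock proteins (5.34), RNA-binding proteins (28.8) and mitochondria-encoded transcripts (6.36) did not. Over 8948 loci the median was -0.32 (-0.325 to -0.316), 9.10% lay above 0, and 22 were higher and 851 lower by at least 1.5-fold. These counts were 252 and 148 after centring and 5 and 184 under a pseudocount of 0.1, and 525 were lower under a minimum of 0.2. The 7 to 14 unchanged loci past the limit in simulated data, which were centred on 0, are no background for them. GRP9, a glycine-rich protein gene (-1.81), AT1G22690 (-1.76, Gini index 0.956 in root), AT2G43150 (-1.76), the jacalin-related lectin JAL34 (-1.70) and AT4G38080 (-1.66) were lowest. TPPI (2.01), AT5G10660 (1.35), AT1G28620 (1.247), FAF1 (1.16), which all had Gini indices above 0.9 in shoot, and LTPG1, a lipid transfer protein (0.79), were highest.

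Reactivity was slightly more unevenly spread along most transcripts in the salt-treated samples of both tissues. Read depth is unknown, so a difference of coverage between salt and control libraries cannot be told apart from an effect of salt. The Gini index was higher with salt in 73.4% of loci in shoot (72.5 to 74.3), with a median difference of 0.0130, and in 66.1% in root (65.1 to 67.0), with a median difference of 0.0081. All 26 photosynthesis transcripts had a higher index with salt in shoot, at a median difference of 0.0565 and percentile 100. The salt and abscisic acid list had a median difference of -0.0150 in shoot and -0.0140 in root, both at percentile 0, and LTI30 went from 0.705 to 0.564 in shoot. In root, aquaporins (-0.0124, percentile 0.13), ion transport genes (-0.0084, percentile 0.66), heat shock proteins (-0.0104, percentile 0.48) and photosynthesis transcripts (-0.0036, percentile 1.18) also stood apart, and chloroplast-encoded transcripts stood at 0.0265 and percentile 99.4.

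The greatest contrast in the Gini index was between tissues. Photosynthesis transcripts had a median index of 0.803 in control roots and 0.516 in control shoots, and of 0.800 and 0.563 with salt, all 26 being higher in root in both. Of the 4 root-expressed markers 3 had the lower index in root in both, with medians of 0.512 in control root and 0.634 in control shoot. A lower index in root was not particular to them. Housekeeping genes were lower in 17 of 20 without salt and 19 of 20 with salt, and ribosomal proteins in 19 and 25 of 25, all at percentile 0. Aquaporins (percentiles 0.17 and 0) and heat shock proteins (0.08 and 0.10) also stood apart on that side. On the higher side with salt stood the salt and abscisic acid list, at 0.0389 relative to all transcripts and percentile 100, with 24 of 30 members above their median. Over all loci the index was close in the tissues, with medians of 0.678 in control roots and 0.679 in control shoots. It was higher in root in 42.0% of loci without salt and 38.4% with salt. Log2 ratio and Gini difference of root against shoot were related over all loci (Spearman's rho 0.551 without salt and 0.568 with salt). A list low in one thus tends to be low in the other.

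**Figure D3:**
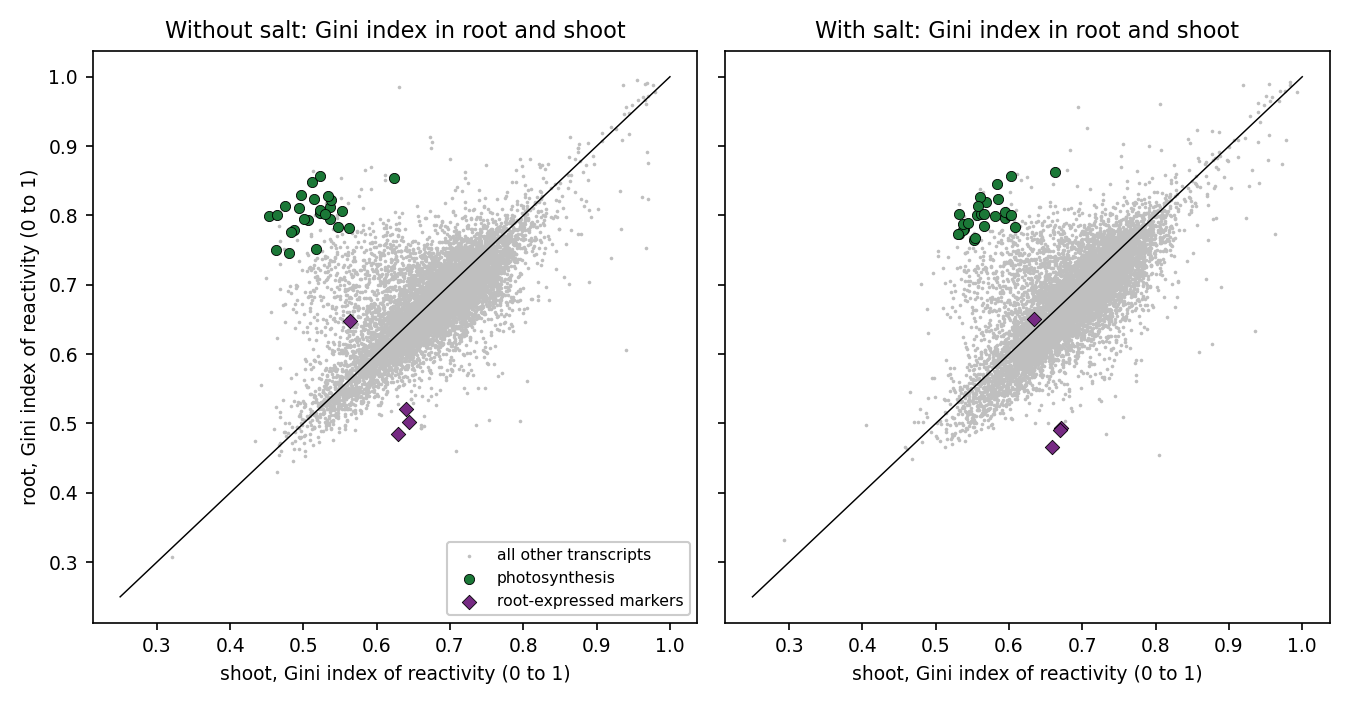
Gini index of DMS reactivity (0 to 1) in shoot (horizontal axis) and root (vertical axis) without salt (left) and with salt (right), for all loci (grey), photosynthesis transcripts (green circles) and root-expressed markers (purple diamonds), with the line of equal values. Photosynthesis transcripts sit above the line, at medians of 0.803 in root against 0.516 in shoot without salt.

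Control shoots differed from the other conditions in how the scores were distributed. The highest reactivity of a transcript was never below 1 in control shoots, over 12978 transcripts, but was below 1 in 67 in salt-treated shoots, 1870 in control roots and 1089 in salt-treated roots. Across loci, mean reactivity and Gini index had a Spearman's rho of -0.993 in control shoots, -0.786 in salt-treated shoots, -0.223 in control roots and -0.279 in salt-treated roots. Every mean-reactivity ratio against control shoots uses these scores and may depend on how they were scaled.

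**Figure D4:**
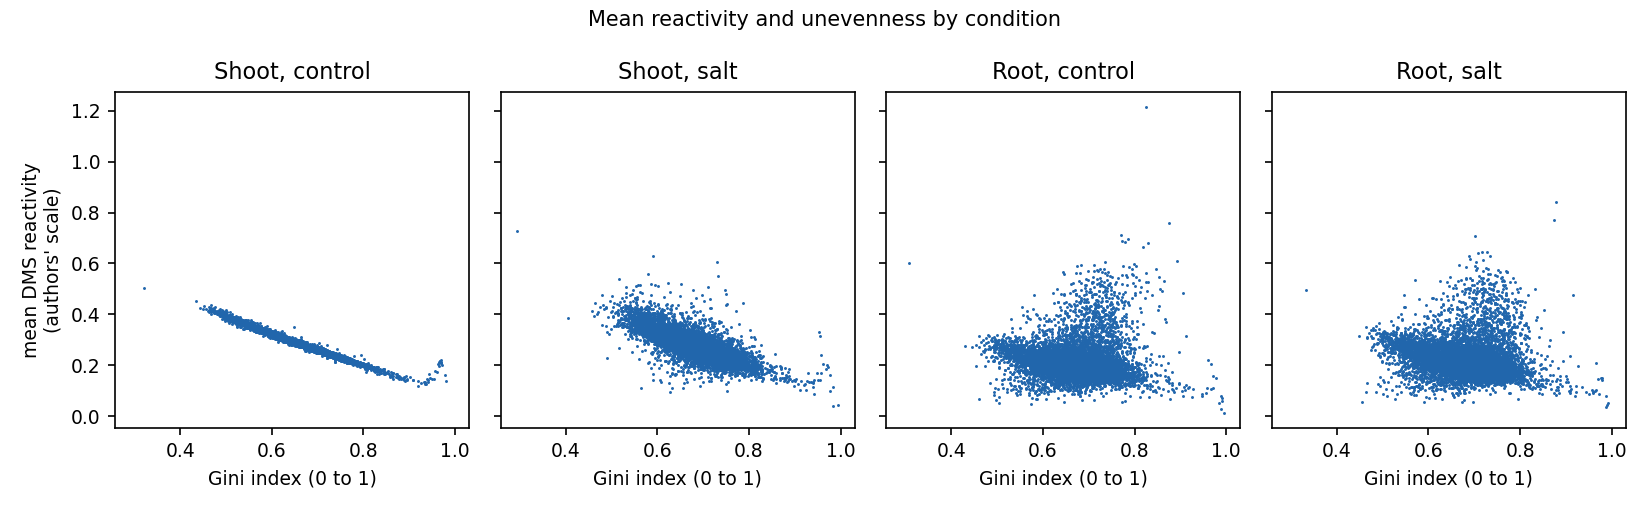
Mean DMS reactivity (vertical axis, on the authors' scale) against the Gini index (horizontal axis, 0 to 1) of each locus in the 4 conditions. Points follow a narrow band in control shoots (rho -0.993) and scatter widely in control roots (rho -0.223).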

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

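All tests in this part were chosen after the results were seen. Nuclear photosynthesis transcripts had a median salt log2 ratio of 0.1283 in shoot, with 25 of 26 members above 0, and of -0.6642 in root, with all 26 below 0, opposite directions whose difference was not tested because the replicates were combined. One scale factor per transcript and condition cannot be told apart from a change in structure as the source of the lower root values, because the list's Gini difference with salt in root was only -0.01169 relative to all transcripts (percentile 1.18), with 18 of 26 members below their median and 8 above. The list was also more uneven in root than in shoot, by 0.2507 in the Gini index relative to all transcripts with salt, which argues against the control root libraries alone for the Gini index. For mean reactivity, the ratio of root over shoot with salt lay at -0.01675 relative to all transcripts, so the control root libraries and a salt effect cannot be told apart. Shallow coverage of leaf-type transcripts in roots, or a difference of RNA structure between tissues, may give the high Gini index, and they cannot be told apart because the table holds no depth; 3 of the 4 root-expressed markers were less uneven in root (list median -0.1233 relative to all transcripts), as either could give, but so were 17 of 20 housekeeping genes.

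Aquaporins had a median salt log2 ratio of -0.1034 in shoot and 0.1967 in root, opposite directions whose difference was not tested. Only the root members were uniform, all 13 above 0. In shoot 8 lay below 0 and 6 above, and that list did not stand apart without matching (percentile 2.5). Chloroplast-encoded transcripts had a median of 0.1045 in shoot (10 of 14 above 0) and -0.259 in root (8 of 14 below 0), also opposite and also not tested, and with a minimum mean reactivity of 0.2 the root list no longer stood apart (percentile 12.8).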

How the results depend on the processing

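No paired analysis was possible because each condition had 1 deposited value per transcript, with the replicates combined; leaving out each replicate and a replicate block were not run for that reason. Depth is unknown, so what it limits could not be measured. All alternatives with values below were planned before the data were examined. Without a minimum, every result kept its direction and stayed within the limits set for no change. The same held for the 2 settings chosen after seeing the data, a Gini index of at most 0.9 and identical loci counted once. Keeping transcripts measured in all 4 conditions could change nothing, since every transcript had a value in each. Of 534 list results over 9 settings, 512 were unchanged in whether they stood apart, 12 stood apart only under the alternative, on the side they were on, and 9 no longer did. Part of the 512 was fixed in advance. The 4-condition setting and centring, which subtracts 1 constant from all ratios, are among the 9 and could not move a list among random lists. Those gained for the difference between tissues were reactive oxygen scavenging (percentile 98.1), housekeeping genes (97.55) and root-expressed markers (low side) with all isoforms, and root-expressed markers (1.05) with a pseudocount of 0.1. With salt they were reactive oxygen scavenging (1.05) with all isoforms and mitochondria-encoded transcripts (low side) without matching, both for root over shoot. In 12 the relative median lay on the other side of 0, none of them for a list that stood apart at first. The remaining result, the salt and abscisic acid list for root over shoot without salt, stood apart with all isoforms on the low side, at -0.0397. Where no construction is named, the cause was not tested.

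With a minimum mean reactivity of 0.2, which leaves fewer loci, 13 loci were lower by 1.5-fold in shoot and 4 higher in root. The root salt median was 0.0953 with 82.2% above 0. The tissue medians were -0.434 without salt (8.68% above 0) and -0.307 with salt (10.4% above 0, 525 lower). The difference between tissues had a median of 0.101, Pearson's r of 0.148 and 4 loci higher. The Gini index was higher in 74.65% in shoot and 64.9% in root. With all isoforms, which adds transcripts, 13 were higher and 59 lower in shoot, and the root median was 0.0912 with 81.0% above 0.

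Centring sets each median to 0 by construction and the share above it to 50% in shoot, 49.994% in root, which turns that share to the other side of an even split, and 50% in both tissue comparisons. The 1.5-fold counts were then 4 higher in root, 433 higher and 180 lower for root over shoot without salt, 252 and 148 with salt, and 15 and 64 for the difference, whose median was 0.001175.

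A pseudocount of 0.1 draws ratios towards 0. The shoot median was -0.0256 with 2 higher and 5 lower, the root median 0.0595 with 1 and 17, the tissue medians -0.317 with 16 and 377 without salt and -0.225 with 5 and 184 with salt, and the difference 0.0848 with 5 higher.

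The lower of the planned size limits gave 55 higher and 187 lower in shoot, 223 and 94 in root, 213 and 6605 between tissues without salt, 191 and 4445 with salt, and 697 and 114 for the difference. The higher, of 2-fold, gave 1 and 5 in shoot, 1 and 5 in root, 5 and 214, 4 and 103, and 4 and 10 in the same order. With the standard deviation over the mean in place of the Gini index, 72.3% of loci were more uneven with salt in shoot.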

Other observations

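All tests and gene families in this part were chosen after the results were seen. Families were formed from symbols with a shared stem and at least 5 members analysed. Outside the middle 99% of matched random lists lay 8 of 161 families for salt in shoot, 8 of 159 for salt in root, 8 of 161 between tissues without salt and 9 of 160 with salt, against 1.61, 1.59, 1.61 and 1.6 from chance. The chance counts treat members as independent, and some families repeat lists fixed in advance. For salt in shoot, 9 of 12 genes of the stem PIP, 6 of 10 of ERD, 3 of 6 of RD and 3 of 9 of UBQ were on those lists. The H2A and H2B histone families lay higher in salt-treated roots, while some members did not. The 9 H2A genes had a median log2 ratio of 0.26 (percentile 99.99), with HTA13 at 0.34 and HTA6 at 0.33, and 8 of them lay above the median of all transcripts, HTA12 at 0.04 below it. The 5 H2B genes had a median of 0.29 (percentile 99.99), with HTB9 at 0.33 and HTB1, below the median of all transcripts, at 0.02. The symbol stem RS, 6 genes with a median of 0.28 (percentile 100), mixes arginine/serine-rich splicing factors, such as RS2Z33 at 0.34 and RS31 at 0.22, with the ribosomal protein gene RS27A at 0.31, and splicing factors were not tested apart. UDP-glucosyltransferases had a median of -0.035 (percentile 0.06), with 8 of 10 genes below the median of all transcripts. The symbol stem ERF had a median of -0.027 (percentile 0.06), with 8 genes below the median of all transcripts and 5 above. It mixes ethylene response factors, such as ERF2 at -0.57 and ERF6 at -0.44, with translation release factors. The latter are ERF1-1 at 0.11, ERF1-2 at 0.27 and ERF1-3 at 0.27, all above that median. Ethylene response factors were not tested apart. The symbol stem HSP had 10 of 12 genes below the median of all transcripts, at -0.096 relative to it (percentile 0.11), whereas the heat shock list fixed in advance, which shares 5 of these genes, did not stand apart in root (percentile 7.90). In shoots, 8 xyloglucan endotransglucosylase/hydrolase genes of the cell wall had a median of 0.15 (percentile 99.93), with XTH9 at 0.48, XTH24 at 0.31 and XTH7 at -0.14.

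Between tissues without salt, the 5 fatty acid desaturases had a median of 0.38 (percentile 99.54), with members on both sides of 0. The plastid enzymes FAD6 (0.59), FAD5 (0.46) and FAD7 (0.38) were more reactive in root, and the endoplasmic reticulum enzymes FAD2 (-0.52) and FAD3 (-0.44) less, although FAD3 lay above the median of all transcripts, and a division by compartment was not tested. All 11 transcripts of mitochondrial complex II subunits lay below that median, at -0.69 (percentile 0.34), with SDH3-1 at -0.81. Calmodulins had a median of -0.63 (8 genes, percentile 0.04), with CAM2 at -0.82. With salt, all 9 transcripts of plastid transcriptionally active chromosome proteins lay above the median of all transcripts, at 0.36 (percentile 99.54), with PTAC18 at 0.50 and PTAC5 at 0.48. Aux/IAA regulators of auxin response (10 genes) had a median of -0.59 (percentile 0), with IAA28 at -0.75 and IAA7 at -0.04. They were mixed, 7 below the median of all transcripts and 3 above.

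The standard deviation of reactivity between bases varied least from locus to locus in control shoots. Its coefficient of variation between loci was 0.146 in salt-treated shoots, 0.421 in control roots and 0.372 in salt-treated roots, but 0.082 in control shoots. Mean reactivity and Gini index had a Spearman's rho of -0.9932 there and of -0.786 to -0.223 in the other conditions, which is consistent with a scale set for each transcript in control shoots. Whether deeper control shoot libraries add to it cannot be told apart, since the coefficient of variation of the Gini index between loci was 1.094 times the lowest of the other conditions (1.087 to 1.103 over 1000 bootstraps of loci), without a spread between replicates. No biological explanation was tested. Mean-reactivity ratios against control shoots may depend on such a scale, and the Gini index would too if the scale came before an upper bound on reactivity, which was not tested.

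The salt and abscisic acid list was lower with salt in shoot in its Gini index also, by -0.02806 relative to all transcripts (percentile 0). One linear scale factor per transcript and condition leaves the Gini index unchanged below an upper bound, so it alone would not give this shift. However, 19 of 30 members lay below the median of all transcripts and 11 above. For the list as a set, such a factor therefore cannot be told apart from other causes of the lower mean. Log2 ratio and Gini difference were related over all shoot loci (Spearman's rho 0.303), and the random lists were not matched on the ratio, so a list low in one tends to be low in the other. In 17 of 30 members both were lower. Deeper coverage of transcripts that salt induces and a change in their structure could each give this, and they cannot be told apart because the table holds no depth. A response of RNA structure to salt stays open and was not tested.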
